A study of Homo sapiens and Mus musculus with 18 samples.

How the data were processed

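Bulk RNA was measured in 10 libraries of the human cell line Met5a and in 8 mouse KPCA tumours. Per the labels' protocols, cells were grown in DMEM with 10% serum, total RNA was extracted with a column kit and a company made and sequenced the libraries. The values used are whole-number counts per gene, as deposited by the authors, with 1 table per species. The authors also deposited FPKM values, which in every library equal the count over gene length times 1 factor for that library. The aligner, the counting tool, strandedness and the genome build are not given in the sources used here. All 58735 human genes have the start and end of GENCODE 29 on GRCh38, so human positions are given on that build. Mouse positions are those in the deposited table. Groups and replicate numbers follow the sample titles. The genotype tag of all 8 tumours reads WT, so the titles alone give the Het and KO groups. Both WT columns carry a suffix that no other column has. It cannot be told apart from the WT group, and what it stands for is not given in the sources used here. No column of per-sample values was left unused (0), and entries without a gene identifier held 0 of the counts. Of the human gene symbols 1566 stand on more than 1 identifier, and 103 of the mouse symbols. The mouse hypoxia list has 23 tested members from 22 symbols because Aldoa stands on a pair of identifiers.

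Total counts ran from 15489888 to 21642906 in the Met5a libraries and from 17746902 to 28070669 in the tumours. A count of 0 allows up to 3 counts, given as CPM of that library. Such limits cover counting error only, because reads without molecular identifiers are not independent molecules. CPM values use library sizes scaled by TMM factors.

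Designs, tests, gene lists and the rule for named genes were fixed before the data were examined. Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10), which left 17175 human genes, 16287 mouse genes, and 15205 for KO against WT and Het pooled. The quasi-likelihood test of edgeR was fitted with 1 coefficient per group over all libraries of a species, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values of single genes are from this test unless another tool is named. Comparisons were V1 with V3, V1 with CTR, V3 with CTR, KO with WT, KO with Het, Het with WT, and KO with the pooled others.

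Of the gene lists, 27 were human and 39 mouse. A list with fewer than 5 tested members was not tested. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry, which tests whether the genes of a list move on balance in 1 direction and compares them with no other genes. Adjusted p-values of lists are from camera with the preset correlation unless stated. A list score of a library is the mean over tested members of log2 CPM (prior count 2) minus the mean of the gene over the libraries of the species. Scores were compared by two-sided exact permutation tests over all arrangements.

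Named genes are AMHR2 and AMH in every comparison. They are also the called protein-coding genes with a mean CPM of at least 5 and groups that do not overlap, up to 8 per direction in V1 with V3 and KO with WT and up to 5 in the others, or the 5 genes with the smallest p where none qualifies, and of the lists described up to 4 called members with the smallest p, or the 2 with the smallest p where none is called. Which lists had members named was narrowed after the results were seen, to the BMP-SMAD targets, the AMH and BMP pathway genes and the passing lists with the smallest p. A gene that this rule names for V1 with V3 is not reported here. ACVR1 in single libraries, Epcam and CALB2 were singled out after their values were seen.

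Alternatives were median-ratio (RLE) factors, no filter except for genes at 0 in every library, DESeq2 1.42.0 (Wald test), limma on log2(FPKM + 1) for genes with an FPKM of at least 1, the compared groups only, each library left out in turn, a replicate block in Met5a, animal numbers under or over 500 as a covariate in the tumours, and a 3-group fit for the pooled comparison. Leaving out V1 1 with CTR 3, whose best correlations are the lowest in Met5a (0.947 and 0.942), or KO543 with WT438, which lie apart on the first components, and summing MAGED4 with MAGED4B were chosen after seeing the data. Fits without a library reran the filter, so changed members can shift list means. A lone sample in a group is taken to vary like other groups. Values of shared controls were set beside 20 simulations in which V1, V3 and CTR libraries were all drawn from 1 mean per gene. A first form, which kept the real controls, left out their chance values and was replaced after the results were seen.

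The scripts were tested on simulated data drawn from the real means, dispersions and library sizes, with 50 genes changed at each of 4 fold sizes. Of 50 genes changed 4-fold, edgeR recovered 30 for V1 with V3 (16741 genes), 30 for V1 with CTR (16741), 25 for V3 with CTR (16755), 21 for KO with WT (15914), 24 for KO with Het (15914), 22 for Het with WT (15893) and 33 for the pooled comparison (14888). At 2-fold it recovered 4, 6, 3, 8, 9, 5 and 17 in the same order. Calls that were false made up 2.6 to 10.4% for edgeR and 14.1 to 32.1% for DESeq2. In a further simulation added after the unfiltered counts were seen, with no gene changed and no filter, edgeR made 17 to 42 false calls per comparison against 0 with the filter. Lists of 20 genes raised 1.5-fold had p from 1.84e-11 to 4.76e-05 with the preset and from 0.000329 to 0.00678 with the estimated correlation, not adjusted over the lists of a comparison. The simulated genes vary independently, so these values can overstate what the estimated correlation finds in real data. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.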

Results

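RNA was sequenced in bulk from 10 libraries of Met5a, an immortalised human pleural mesothelial cell line, and from 8 mouse KPCA tumours. AMHR2 is the type II receptor of anti-Müllerian hormone (AMH), a ligand of the TGF-beta family that signals through BMP-type SMAD proteins. The Met5a libraries were 3 controls (CTR), 4 from cells given the V1 form of AMHR2, described in the series as active, and 3 from cells given the V3 form, described as inactive. KPCA is a mouse model line of high-grade serous ovarian carcinoma, built from fallopian tube epithelium. The tumours were named for wild-type mice (WT, 2), Amhr2 heterozygous mice (Het, 2) and Amhr2 knock-out mice (KO, 4). Total counts were 21300929, 18694540 and 16405711 for CTR 1 to 3, 15489888, 19996052, 21642906 and 18356358 for V1 1 to 4, and 21380452, 17538318 and 17128452 for V3 1 to 3. They were 28070669 for WT438, 17746902 for WT568, 19075680 for Het563, 18270519 for Het569, 18605392 for KO437, 18861875 for KO445, 18705918 for KO479 and 19895517 for KO543. The labels do not say whether Met5a libraries of a group came from separate cultures. Each tumour carries its own number, taken here as an animal number, which the labels do not explain. The p-values measure only the spread between these samples, which may be technical. Mitochondrial transcripts took 5.09% of the counts in CTR 3 and 4.93% in V1 1, against 3.22 to 4.17% in the other Met5a libraries, and 4.87% in WT438 and 4.33% in KO543, against 1.22 to 2.32% in the other tumours.

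The introduced receptor was measured in every Met5a library. AMHR2 (ENSG00000135409, chromosome 12, 53423855 to 53431534, GRCh38) had 0 counts in all 3 CTR libraries, which allows up to 0.14, 0.168 and 0.177 CPM, the count scaled to the effective library size, taking 3 counts as the limit of a count of 0. It reached 68.1, 20.6, 1.98 and 5250 CPM in V1 1 to 4 and 6060, 61.8 and 2.72 CPM in V3 1 to 3. The lowest V1 library was therefore at least 11.2-fold and the lowest V3 library at least 15.4-fold higher than the largest of the CTR limits. Within groups the level spanned 2650-fold among the V1 libraries (1336 ± 2612 CPM, SD, n = 4) and 2230-fold among the V3 libraries (2042 ± 3481 CPM, SD, n = 3). V1 and V3 did not differ in AMHR2 beyond this spread, with a log2 fold change of -0.61 (SE 2.30, edgeR adjusted p = 0.997), and the value ran from -6.07 to 5.36 when single libraries were left out (5.36 without V3 1). The ligand AMH (ENSG00000104899, chromosome 19, 2249309 to 2252073) was present without the receptor, at 47.8 ± 13 CPM in CTR (SD, n = 3), 51 ± 8.57 in V1 (n = 4) and 50 ± 11.3 in V3 (n = 3). ACVR1 (ENSG00000115170, chromosome 2, 157736444 to 157875862), a type I receptor of AMH and BMP ligands, stood at 26.6, 26.4 and 27.2 CPM in CTR 1 to 3. It stood at 575, 84.4, 49 and 5670 CPM in V1 1 to 4 and at 7200, 327 and 79.7 CPM in V3 1 to 3. Every V1 and V3 library lay above every CTR library, the lowest by 1.8-fold. The edgeR log2 fold changes of ACVR1 were 5.90 for V1 (SE 1.96, adjusted p = 0.571) and 6.57 for V3 (SE 2.05, adjusted p = 1.00, and 2.93 without V3 1), neither past the threshold. Two-sided exact permutation tests of log2 CPM gave p = 0.0857 for V1 over 35 arrangements and p = 0.1 for V3, the smallest that 20 arrangements can give. ACVR1 belonged to a list fixed beforehand, but it was singled out after its values were seen.

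**Figure D1:**
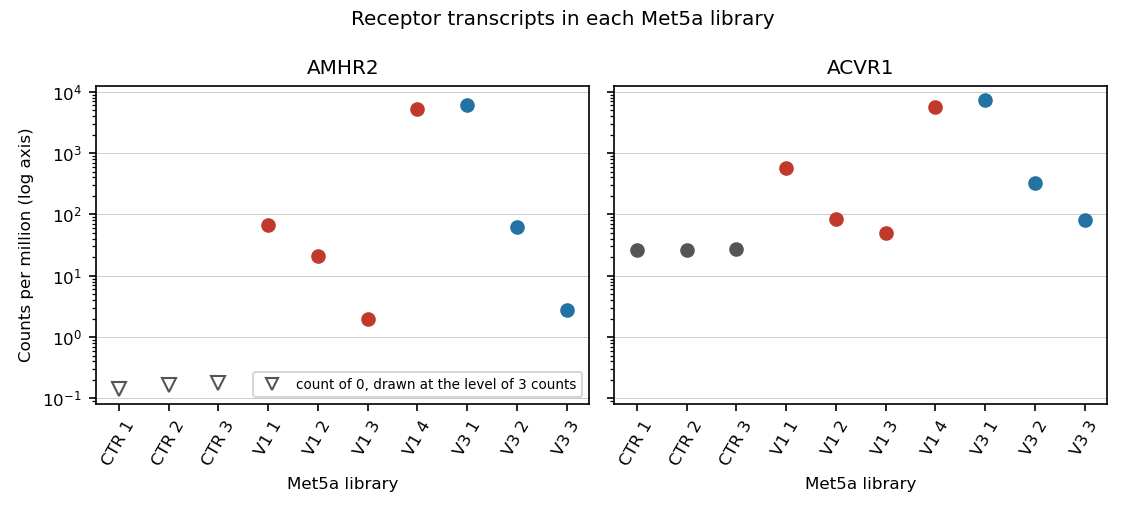
Levels of AMHR2 and ACVR1 in each Met5a library, in CPM on a log axis, with 1 point per library of the CTR, V1 and V3 groups and open triangles at the limit of 3 counts where AMHR2 had none. AMHR2 runs from 1.98 to 5250 in V1 and from 2.72 to 6060 in V3, and ACVR1 lies between 26.4 and 27.2 in CTR and between 49 and 7200 in the other libraries.

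The comparison of V1 with V3 asked which genes follow the active form of the receptor. Interferon-stimulated genes averaged higher and cytokine and chemokine genes lower in V1 cells, which passed only with the preset correlation (adjusted p = 0.897 with an estimated correlation for both). Of 28 interferon-stimulated genes, 27 were higher in V1 (median log2 fold change 0.97), among them the antiviral GTPase MX1 (chromosome 21, 41420304 to 41459214), at 89.9 ± 79.5 CPM in V1 (SD, n = 4) and 32.4 ± 20.7 in V3 (n = 3). DDX58, which encodes the RNA sensor RIG-I (chromosome 9, 32455705 to 32526324), was at 98.5 ± 90.2 and 31.3 ± 9.40 CPM. Of 16 cytokine and chemokine genes 11 were lower in V1 (median -1.65), including the neutrophil chemokine CXCL6 (chromosome 4, 73836497 to 73849064) at 4.08 ± 3.69 against 15.8 ± 8.48 CPM and the monocyte chemokine CCL2 (chromosome 17, 34255218 to 34257203) at 0.114 ± 0.126 against 1.5 ± 0.922 CPM. Of 13 class I antigen presentation genes, 12 were higher (median 0.53). HLA-E (chromosome 6, 30489467 to 30494205) was at 182 ± 59.6 against 123 ± 12.9 CPM and the peptide transporter TAP2 (chromosome 6, 32821833 to 32838780) at 47.1 ± 21.0 against 29.4 ± 7.91 CPM. Direct targets of BMP-SMAD signalling did not pass: 12 of 16 were higher (median 0.48, camera adjusted p = 0.229). BAMBI (chromosome 10, 28677342 to 28682939), a decoy receptor, was at 16.7 ± 4.25 against 9.40 ± 4.43 CPM and the inhibitory SMAD6 (chromosome 15, 66702228 to 66782848) at 48.0 ± 6.12 against 30.5 ± 7.99 CPM. The AMH and BMP pathway genes gave a median of -0.04 (adjusted p = 0.748). INHBB (chromosome 2, 120346143 to 120351808), an activin subunit, was at 31.1 ± 20.01 against 10.4 ± 6.58 CPM and BMP7 (chromosome 20, 57168748 to 57266629) at 3.27 ± 1.25 against 9.66 ± 6.78 CPM. Single libraries moved several log2 fold changes, namely MX1 (0.72 from 1.47) and DDX58 (1.00 from 1.66) without V1 2, BMP7 (-0.87 from -1.56) without V3 2, and BAMBI (1.26 without V3 1 and 0.55 without V3 3, from 0.82).

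No gene was called between V1 and V3 by edgeR. V1 4 and V3 1, on opposite sides of this comparison, were the most alike of all Met5a pairs (r = 0.991). The lack of calls therefore does not show that the 2 forms act alike. The 2 groups did not overlap in 845 genes (4.92%), where chance gives 5.71%. The edgeR quasi-likelihood test called 0 of 17175 genes, with 689 at an unadjusted p under 0.05 where chance alone gives 859, limma on FPKM called 0, DESeq2 called 1, and 1 list member was called when adjusted over the list alone. Without V1 4 edgeR called BICC1, PCDHGB5 and PDPN, all lower in V1 (smallest adjusted p = 0.00582). The count at an unadjusted p under 0.05 was 1161 without V1 4 and 1214 without V3 1, both above 859, and 362 without V3 2 and 221 without V3 3. Genes do not vary independently. Other splits of these libraries, fitted without CTR, gave up to 2800 such genes (median 696). No splits were run without V1 4 or V3 1, so those counts decide nothing. Among the genes with the smallest edgeR p, C4orf19 (chromosome 4, 37453941 to 37623495) had a log2 fold change of -2.28 (SE 0.51, adjusted p = 0.985). ESM1, an endothelial secreted proteoglycan (chromosome 5, 54977864 to 55022671), had 0 counts in 3 of the 4 V1 libraries and 0.747, 6.78 and 0.809 CPM in V3. The lincRNA genes AC048341.1 (1.57, SE 0.38) and AC008556.1 (-3.85, SE 0.94) were also among them, at an adjusted p = 0.985. In camera tests with the preset inter-gene correlation, 3 of 25 lists passed, namely cytokines and chemokines (adjusted p = 0.000409), interferon-stimulated genes (adjusted p = 0.000409) and class I antigen presentation (adjusted p = 0.0412). Each had adjusted p = 0.897 with an estimated correlation, and the other 22 lists had adjusted p from 0.0811 to 0.852. All 4 V1 libraries had a lower mean cytokine score than all 3 V3 libraries, a difference of -1.05 (exact permutation p = 0.0286 over 35 arrangements, the smallest possible), which was 1 of 25 such tests. Without V3 2 the mean log2 fold change of the cytokine list was -0.28 in place of -0.88. The interferon score was -2.18, 1.76 and 0.859 in V1 1 to 3 (exact permutation p = 0.771 for V1 against V3), and without V1 2 the mean log2 fold change of that list was 0.31 and it no longer passed. The class I list was lost without V1 2 (mean 0.22), V1 3 (0.17), V3 1 (0.39) or V3 3 (0.39), from 0.40, and reached 0.62 without V1 1.

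**Figure D2:**
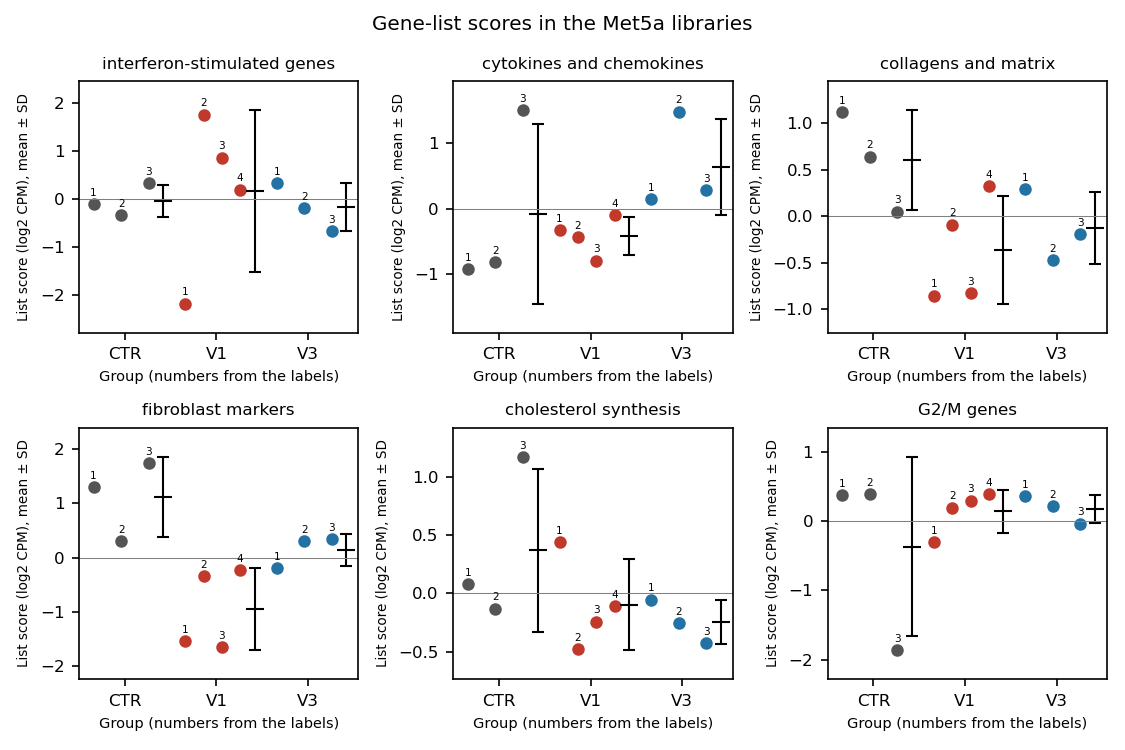
Scores of 6 gene lists in the Met5a libraries, each score being the mean over list members of log2 CPM centred on the mean of the gene over all 10 libraries, with 1 numbered point per library and bars showing the group mean ± SD. Cytokine and chemokine scores lie lower in V1 than in V3 by 1.05 log2 units, interferon scores of V1 run from -2.18 to 1.76, and CTR 3 lies at -1.86 in G2/M genes and at 1.17 in cholesterol synthesis.

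V1 cells were next compared with the CTR libraries, which carried no receptor reads. Collagen and matrix genes, fibroblast markers and cholesterol synthesis genes were lower in V1, and immediate-early, YAP-TEAD target and interferon-stimulated genes were higher. These lists passed only with the preset correlation (adjusted p from 0.0706 to 0.721 with an estimated correlation), the cholesterol list rested on CTR 3 and the interferon score was at -2.18 in V1 1 (exact permutation p = 0.857). V1 4 held the most AMHR2 of the V1 libraries. Its collagen (0.324), cholesterol (-0.107), immediate-early (-0.104) and interferon (0.196) scores lay inside the range of the CTR libraries. Its fibroblast (-0.237) and YAP-TEAD (0.389) scores lay outside that range. Of 21 collagen and matrix genes 20 were lower (median log2 fold change -0.51). COL6A3 (ENSG00000163359, chromosome 2, 237324003 to 237414375), a chain of collagen VI, was at 1.42 ± 0.577 CPM in V1 (SD, n = 4), while CTR 1 held 171 CPM and CTR 2 and CTR 3 held 2.08 and 10.1. The collagen cross-linking enzyme LOX (chromosome 5, 122063195 to 122078360) was at 1.84 ± 1.26 against 21.2 ± 28.1 CPM. All 6 fibroblast markers were lower (median -2.17). The proteoglycan DCN (chromosome 12, 91140484 to 91183123) was at 0.589 ± 0.677 against 4.58 ± 1.65 CPM and CD34 (chromosome 1, 207880972 to 207911402) at 0.602 ± 0.345 against 4.86 ± 3.90 CPM. DCN also belongs to the collagen list. In cholesterol synthesis 22 of 23 genes were lower (median -0.45), such as squalene synthase FDFT1 (chromosome 8, 11795573 to 11839309) at 50.3 ± 10.6 against 100.5 ± 53.9 CPM and MSMO1 (chromosome 4, 165327623 to 165343160) at 27.9 ± 5.63 against 87.0 ± 96.0 CPM. The log2 fold change of MSMO1 was -0.19 without CTR 3 in place of -1.64. Of 15 immediate-early genes 14 were higher (median 0.40). NR4A1 (chromosome 12, 52022832 to 52059507) was at 29.5 ± 6.78 against 12.9 ± 4.47 CPM and the AP-1 component JUN (chromosome 1, 58780788 to 58784327) at 384 ± 280 against 121 ± 21.2 CPM. Of 8 YAP-TEAD targets 7 were higher (median 0.46). Tissue factor F3 (chromosome 1, 94529225 to 94541800) was at 280.5 ± 124 against 82.7 ± 56.6 CPM and the receptor kinase AXL (chromosome 19, 41219203 to 41261766) at 583 ± 117 against 345 ± 127 CPM. Without CTR 1 the log2 fold change of COL6A3 was -2.09 in place of -5.43 and that of LOX -1.44 in place of -3.54. FDFT1 was at -0.47 without CTR 3 in place of -0.997 and JUN at 1.01 without V1 1 in place of 1.67.

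The lists that passed in V1 against CTR were collagens and matrix (camera adjusted p = 1.58e-06, adjusted p = 0.436 with an estimated correlation), cholesterol synthesis (3.23e-05, adjusted p = 0.721 with an estimated correlation), fibroblast markers (5.64e-05, adjusted p = 0.0706 with an estimated correlation), immediate-early genes (5.64e-05, adjusted p = 0.298 with an estimated correlation) and YAP-TEAD targets (0.00057, adjusted p = 0.406 with an estimated correlation). G2/M genes (22 of 24 higher, adjusted p = 0.00057), DNA replication genes (21 of 21 higher, 0.000801) and interferon-stimulated genes (22 of 28 higher, 0.00909) also passed, each with adjusted p = 0.721 with an estimated correlation. The other 17 lists had adjusted p from 0.088 to 0.665, among them BMP-SMAD targets (9 of 16 higher, median 0.19, adjusted p = 0.354). MSX1 (chromosome 4, 4859666 to 4863936) was at 25.4 ± 15.0 against 12.0 ± 3.60 CPM and the BMP antagonist GREM1 (chromosome 15, 32717974 to 32745107) at 1317 ± 435 against 456 ± 399 CPM (log2 fold change 1.53, and 2.33 without CTR 2 and 0.99 without CTR 3). INHBB, from the AMH and BMP pathway list (median -0.01, adjusted p = 0.609), stood at 31.1 ± 20.01 against 4.94 ± 2.63 CPM (log2 fold change 2.65, SE 0.63, adjusted p = 0.569). The fibroblast score was lower in all 4 V1 than in all 3 CTR libraries by -2.06 (exact permutation p = 0.0286 over 35 arrangements, 1 of 25 such tests). CTR 3 stood apart, with a G2/M score of -1.86, a cholesterol score of 1.17 and 5.09% mitochondrial counts. Without CTR 3 the mean log2 fold change of G2/M genes turned from 0.24 to -0.20, that of DNA replication genes went from 0.25 to 0.02 and that of cholesterol genes from -0.55 to 0.01, and only the turned G2/M list still passed. DNA replication was also lost without V1 1 (0.12), and the interferon list without CTR 2 (0.74), V1 2 (0.19, with the test turned down) or V1 3 (0.84), from 0.86. Collagens still passed without CTR 1, at a mean of -0.63 in place of -1.10. Some means grew, immediate-early genes from 0.62 to 1.11 without CTR 1 and fibroblast markers from -1.82 to -2.88 without CTR 2. G2/M genes reached 0.52, 0.53 and 0.36 without CTR 1, CTR 2 or V1 1, and DNA replication genes 0.39 and 0.41 without CTR 1 or CTR 2.

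Only 1 of 17175 genes was called in V1 against CTR by edgeR, MAGED4 (ENSG00000154545, chromosome X, 52184823 to 52192268), a member of the MAGE family, which fell by 3.70 on the log2 scale (SE 0.42, adjusted p = 0.028). It measured 17.8, 14.0 and 15.2 CPM in CTR and 0.753, 1.29, 2.07 and 0.637 CPM in V1. The call is uncertain because MAGED4B is a near-identical copy that may share its reads. With the counts of both summed, the fold change was -1.58 (SE 0.60, adjusted p = 0.606) and no gene was called. At an unadjusted p under 0.05 there were 1325 genes where chance gives 859, and 879 without V1 3. With only the compared groups fitted the count was 993, reached by 13 of 35 splits of these libraries, the real split included. The count is therefore no evidence of a difference. DESeq2 called 66 genes (40 higher) and limma on FPKM called 1. When adjusted over the list alone, 20 list members were called against 0 over all genes, 4 of them collagens, 3 fibroblast markers and 3 mesothelial markers. The edgeR count was 0 without CTR 1, CTR 2, CTR 3, V1 1 or V1 2 and 6 without V1 4. It was also 0 with only the compared groups fitted (smallest adjusted p = 0.225).

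V3 cells, which carry the form described as inactive, were compared with the same CTR libraries. Cholesterol synthesis genes were lower in 22 of 23 cases (median log2 fold change -0.84). This list and the others described here passed only with the preset correlation (adjusted p from 0.179 to 0.492 with an estimated correlation), BMP-SMAD and AMH and BMP pathway genes not at all. Farnesyl pyrophosphate synthase FDPS (chromosome 1, 155308748 to 155320666) was at 42.0 ± 6.06 CPM in V3 (SD, n = 3) against 75.1 ± 31.3 in CTR (n = 3) and MSMO1 at 24.0 ± 3.72 against 87.0 ± 96.0 CPM. Of 15 immediate-early genes 12 were higher (median 0.66). EGR1 (chromosome 5, 138465490 to 138469315) was at 43.1, 133 and 459 CPM in V3 1 to 3 against 34.9 ± 19.2 in CTR and KLF2 (chromosome 19, 16324817 to 16327874) at 40.2 ± 19.9 against 12.7 ± 5.23 CPM. Of 8 YAP-TEAD targets 7 were higher (median 0.49), with AMOTL2 (chromosome 3, 134355874 to 134375479) at 298 ± 30.6 against 206 ± 29.1 CPM and F3 at 220 ± 120 against 82.7 ± 56.6 CPM. Feedback genes of ERK signalling were higher in 7 of 11 cases (median 0.36). The phosphatase DUSP4 (chromosome 8, 29333064 to 29350668) was at 248 ± 40.9 against 134 ± 40.3 CPM and PHLDA1 (chromosome 12, 76025447 to 76033932) at 341 ± 56.3 against 173 ± 64.2 CPM. Of 21 collagen and matrix genes 16 were lower (median -0.41) and of 6 fibroblast markers 5 were lower (median -1.51). BMP-SMAD targets showed a median of -0.02 (9 of 16 lower, adjusted p = 0.843). BAMBI was at 9.40 ± 4.43 against 21.97 ± 15.8 CPM and SMAD7 (chromosome 18, 48919853 to 48952052) at 20.1 ± 9.17 against 30.4 ± 3.70 CPM. The AMH and BMP pathway list had a median of 0.04 (adjusted p = 0.327). Without CTR 3 FDPS had a log2 fold change of -0.45 in place of -0.84, without V3 3 EGR1 had 1.35 in place of 2.60, and without CTR 1 BAMBI had -0.44 in place of -1.22. F3 ran to 2.15 without CTR 2 and 0.92 without V3 1 from 1.41, and SMAD7 to -1.04 without V3 1 and -0.39 without V3 3 from -0.60.

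In V3 against CTR 10 of 25 lists passed with the preset correlation. These were cholesterol synthesis (camera adjusted p = 2.83e-12, adjusted p = 0.334 with an estimated correlation), immediate-early genes (2.66e-06) and YAP-TEAD targets (1.59e-05), both with adjusted p = 0.179 with an estimated correlation, ERK feedback genes (0.000747, adjusted p = 0.235 with an estimated correlation), collagens (0.00168, adjusted p = 0.492 with an estimated correlation) and fibroblast markers (0.00341, adjusted p = 0.179 with an estimated correlation). The remaining 4 lists included G2/M genes (23 of 24 higher, median 0.23, adjusted p = 6.11e-05, adjusted p = 0.558 with an estimated correlation). HMMR (chromosome 5, 163460203 to 163491945) was at 91.2 ± 7.24 against 61.7 ± 40.7 CPM and AURKA (chromosome 20, 56369389 to 56392337) at 254 ± 47.7 against 176 ± 111 CPM, their log2 fold changes of 0.56 and 0.53 falling to 0.11 for HMMR and 0.0967 for AURKA without CTR 3, and rising to 0.99 for HMMR without CTR 1 and 0.92 for AURKA without CTR 2. The others were cytokines and chemokines (11 of 16 higher, 0.0128), TGF-beta response genes (15 of 20 lower, 0.0282), both with adjusted p = 0.492 with an estimated correlation, and DNA replication (16 of 21 higher, 0.0281, adjusted p = 0.713 with an estimated correlation). The other 15 lists had adjusted p from 0.055 to 0.843, and 3 libraries against 3 cannot give an exact permutation p under 0.1. CTR 3, whose cytokine score was 1.5, again decided the cell cycle lists, since without it G2/M genes had a mean log2 fold change of -0.18 in place of 0.25 and DNA replication genes -0.08 in place of 0.14. It also set most of the cholesterol difference, which still passed without CTR 3 but at a mean of -0.18 in place of -0.75, with MSMO1 at -0.39 in place of -1.86. Immediate-early genes went from 0.69 to 0.39 without V3 3 and to 1.19 without CTR 1. Collagens were lost without V3 2 (-0.81 from -0.96) and still passed at -0.49 without CTR 1. DNA replication was lost without V3 1 (0.11). Cytokines were lost without CTR 1 (0.01), CTR 2 (0.04) or V3 2 (-0.26), from 0.32, and rose to 1.91 without CTR 3 and 0.53 without V3 3. TGF-beta response genes were lost without CTR 1 (-0.13), CTR 2 (-0.12), V3 2 (-0.21) or V3 3 (-0.12), from -0.26, and reached -0.56 without V3 1. Fibroblast markers went from -1.33 to -2.36 without CTR 2 and -2.10 or lower without V3 1, 2 or 3. The filter then kept more genes. G2/M genes were at 0.54, 0.55 and 0.15 without CTR 1, CTR 2 or V3 1, and DNA replication genes at 0.29 and 0.31 without CTR 1 or CTR 2. The edgeR test called 0 genes, with 727 at an unadjusted p under 0.05 where chance gives 859 (1101 without V3 1, 318 without V3 2 and 449 without V3 3), DESeq2 called 9, limma on FPKM 1, and 5 list members were called when adjusted over the list alone. The smallest p-values belonged to MAGED4 (log2 fold change -3.85, SE 0.47, adjusted p = 0.0658, with MAGED4B summed -2.99, SE 0.70) and TNFAIP3 (chromosome 6, 137867188 to 137883312), which encodes the NF-kB inhibitor A20 (1.17, SE 0.20, adjusted p = 0.765). They were followed by COL6A3 at 0.363 ± 0.332 CPM (-7.33, and -3.99 without CTR 1), PIK3C2B (chromosome 1, 204422628 to 204494724, -1.06, SE 0.23) and ADGRG1 (chromosome 16, 57610652 to 57665580, 1.44, SE 0.32), the last 3 at an adjusted p = 1.00.

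V1 and V3 were compared with the same 3 CTR libraries, so their fold changes share chance values. Across the 17175 genes, which are not independent replicates, the correlation of the 2 sets of fold changes was 0.657, against 0.536 in 20 simulations in which V1, V3 and CTR did not differ, and the covariance was 0.268 against 0.15, a difference of 0.118. The same sign was found for 69.8% of genes against 67.9% in the simulations, and 314 genes had an unadjusted p under 0.05 in both, with the same sign, against 196. The shared controls alone thus give most of the covariance, and the simulated genes vary independently, so the spread of the simulations is too narrow for a test. No gene was called in both by edgeR. DESeq2 called 4 in both, 1 higher and 3 lower, where independent lists of those sizes give 0.00452 and 0.00367, values that leave out the shared controls. The simulations already include shared controls, but real controls that vary more than simulated ones could still give part of the excess. The 3 controls cannot be split into parts of 2 to check this. The simulations also drew V1 and V3 libraries independently, while V1 4 and V3 1 were more alike than any other Met5a pair (r = 0.991). Such a pair can add to the covariance.

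In the KPCA tumours the targeted gene was read first. Amhr2 (ENSMUSG00000023047, chromosome 15, 102445367 to 102454633 in the deposited table, whose mouse build is not given in the sources used here) had 0 and 5 counts in WT438 and WT568, 11 and 5 in Het563 and Het569, and 8, 11, 3 and 3 in KO437, KO445, KO479 and KO543. These are at most 0.583 CPM, near the limit of 0.119 to 0.164 CPM that a count of 0 allows, so the gene does not check the genotype labels at this depth. Its log2 fold change was 1.40 for KO against WT (SE 1.23, edgeR adjusted p = 0.951, 0.34 without WT438 and 5.75 without WT568) and -0.31 for KO against Het (SE 1.07, adjusted p = 1.00). Amh (ENSMUSG00000035262, chromosome 10, 80805243 to 80807648) had 5 to 14 counts per tumour and was too low to be tested. Acvr1 (chromosome 2, 58388644 to 58567157) stood at 63.7 ± 5.79 CPM in WT (SD, n = 2), 81.6 ± 0.962 in Het (n = 2) and 98.3 ± 21.4 in KO (n = 4).

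KO tumours were compared with WT tumours to ask what follows the loss of the receptor in the host. That KO means such a loss rests on the titles alone, because the genotype tag of all 8 tumours reads WT and the Amhr2 counts are too few to check it. Interferon-stimulated and class I antigen presentation genes were lower and collagen and matrix genes higher in KO. These lists passed only with the preset correlation (adjusted p = 0.507, 0.507 and 0.338 with an estimated correlation), and KO543 had the lowest interferon, class I and macrophage scores (-1.81, -1.28 and -0.994). Both WT columns carry a suffix that no other column has, and what it stands for cannot be told apart from the WT group. All 23 collagen and matrix genes were also higher in Het than in WT. The mean log2 fold change of that list was 0.12 for KO against Het. Of 30 interferon-stimulated genes 29 were lower (median log2 fold change -0.77). Ifit1 (chromosome 19, 34640871 to 34650009) was at 47.2 ± 25.9 CPM in KO (SD, n = 4) against 123 ± 31.6 in WT (n = 2) and Rtp4 (chromosome 16, 23520291 to 23614222) at 32.9 ± 14.6 against 70.4 ± 8.06 CPM. All 15 class I genes were lower (median -0.61). The immunoproteasome subunit gene Psmb10 (chromosome 8, 105935735 to 105938444) was at 58.3 ± 9.41 against 77.9 ± 3.59 CPM and Psmb8 (chromosome 17, 34197721 to 34201454) at 41.9 ± 13.1 against 65.8 ± 9.17 CPM. Of 23 collagen and matrix genes 22 were higher (median 0.45). The laminin subunit Lamc1 (chromosome 1, 153218922 to 153332786) was at 453 ± 53.1 against 304 ± 31.6 CPM and Col12a1 (chromosome 9, 79598991 to 79718831) at 505 ± 112 against 307 ± 2.28 CPM. All 11 ERK feedback genes were higher (median 0.36). Dusp4 (chromosome 8, 34807297 to 34819894) was at 150.5 ± 37.2 against 70.4 ± 5.91 CPM and Spred2 (chromosome 11, 19924375 to 20024026) at 94.6 ± 15.5 against 69.9 ± 20.5 CPM. The hypoxia and glycolysis list held 12 genes higher and 11 lower (median 0.05), the hypoxia-induced genes Ankrd37 (chromosome 8, 45996902 to 46005707) and Kdm3a (chromosome 6, 71588972 to 71632990) standing at 14.4 ± 1.97 against 5.15 ± 1.82 and 76.6 ± 2.56 against 50.1 ± 4.98 CPM. Of 24 G2/M genes 23 were lower (median -0.23). Ccna2 (chromosome 3, 36564865 to 36572150) was at 86.2 ± 10.5 against 114 ± 19.3 CPM and Aurkb (chromosome 11, 69045647 to 69051664) at 33.0 ± 5.11 against 44.0 ± 2.72 CPM. BMP-SMAD targets did not pass (9 of 14 higher, median 0.32, adjusted p = 0.0555). Runx2 (chromosome 17, 44495987 to 44814797) was at 65.2 ± 8.83 against 47.5 ± 2.27 CPM and Smad7 (chromosome 18, 75367529 to 75395935) at 66.5 ± 11.9 against 46.5 ± 5.92 CPM. Spred2 had a log2 fold change of 0.17 without WT438 and 0.77 without WT568 in place of 0.44, and Ccna2 of -0.22 without WT568 in place of -0.40.

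With the preset correlation, 18 of 38 lists passed in KO against WT, and none passed with an estimated correlation or with fry. The interferon list had camera adjusted p = 1.1e-16, class I genes 7.99e-09, mitochondrially encoded genes 7.39e-06 (12 of 12 lower), G2/M genes 6.27e-05, hypoxia genes 7.35e-05, and ERK feedback genes and pancreas, liver and gut markers 0.000147 each, all with adjusted p = 0.507 with an estimated correlation. Collagens had 1.89e-11 and adjusted p = 0.338 with an estimated correlation, and their score was higher in all 4 KO than in both WT tumours (difference 0.407, exact permutation p = 0.0667 over 15 arrangements, the smallest possible). TGF-beta response genes (0.000211, 15 of 20 higher), DNA replication (0.000439, 18 of 21 lower), endothelial markers (0.00124, 10 of 11 lower), immediate-early genes (0.00469, 11 of 15 higher), AMH and BMP pathway genes (0.0125, 17 of 24 higher), cytotoxic cell markers (0.0292, 8 of 8 lower) and matrix proteases (0.0423, 11 of 17 higher) each had adjusted p = 0.507 with an estimated correlation. Macrophage markers (0.00071, 16 of 20 lower) and T cell markers (0.00537, 12 of 15 lower) had adjusted p = 0.509 with an estimated correlation, epithelial markers (0.0285, 10 of 10 higher) adjusted p = 0.667 with an estimated correlation. The other 20 lists had adjusted p from 0.0509 to 0.987 with the preset correlation. From the AMH and BMP pathway list, the activin subunit gene Inhba (chromosome 13, 16011851 to 16031621) was at 234 ± 79.5 against 124 ± 20.7 CPM and Inha (chromosome 1, 75507077 to 75510366) at 0.731 ± 0.248 against 0.0783 ± 0.111 CPM, a log2 fold change of 3.23 that was 6.87 for Inha without WT568.

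Several of these lists depended on single tumours. WT438 held mt-Nd1 (chromosome MT, 2751 to 3707) at 8639 CPM and mt-Nd6 (chromosome MT, 13552 to 14070) at 3320 CPM against 2890 and 901 in WT568. Without WT438 mt-Nd1 had a log2 fold change of -0.0615 in place of -1.06 and mt-Nd6 of 0.15 in place of -1.08, and without WT568 they had -1.65 and -1.73. Without WT438 the mitochondrial list turned from a mean log2 fold change of -0.77 to 0.15, while endothelial markers (-0.09 from -0.35) and epithelial markers (2.90 from 2.52) were lost. WT568 had the highest T cell and cytotoxic cell scores (1.17 and 1.26), and without it these lists turned from -0.85 to 1.01 and from -0.96 to 1.55, G2/M genes turned from -0.24 to 0.08 and hypoxia genes from 0.25 to -0.00379. Class I genes (-0.25 from -0.59), ERK feedback (0.48), TGF-beta response (0.36), DNA replication (-0.14), macrophage markers (-0.14), immediate-early genes (0.95), matrix proteases (0.59), AMH and BMP pathway genes (0.73) and epithelial markers (4.40) were also lost without WT568. KO543 stood apart in the KO group, with interferon, class I and macrophage scores of -1.81, -1.28 and -0.994, an epithelial score of 3.75 and Epcam at 119 CPM against 0.053 to 1.75 in the other 7 tumours. Without KO543 the epithelial list (0.06), macrophage markers (-0.14), endothelial (-0.21), T cell (-0.63) and cytotoxic cell (-0.87) markers, immediate-early genes (0.53), matrix proteases (0.21) and AMH and BMP pathway genes (0.28) were lost, as were cytotoxic cell markers without KO445 (-0.76). Other means moved while still passing. Without WT438 these were G2/M genes (-0.49), hypoxia genes (0.66), T cell markers (-1.37) and cytotoxic cell markers (-1.59), without WT568 the mitochondrial list (-1.40), without KO543 the mitochondrial list (-1.26), class I genes (-0.36) and ERK feedback genes (0.26), and without KO437 DNA replication genes (-0.11 from -0.18). The interferon list, collagens and pancreas, liver and gut markers passed whichever tumour was left out, the last going from -1.15 to -2.28 without KO479. Those organ markers were low and uneven, 7 of 11 being lower in KO (median -1.24). The trypsin gene Try4 (chromosome 6, 41302269 to 41305532) was at 2.38 and 4.80 CPM in WT against 0 to 0.79 in KO and the lipase Pnlip (chromosome 19, 58670365 to 58681786) at 3.77 and 10.9 against 0 to 1.95 CPM. Without KO479 Try4 went from -3.96 to -6.42 and Pnlip from -3.65 to -5.82.

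The edgeR test called 0 of 16287 genes in KO against WT, with 648 at an unadjusted p under 0.05 where chance gives 814. That count was 3091 without WT568, 1386 with the animal-number covariate and 421 with only the compared groups fitted. DESeq2 called Ankrd37 and Ddit4, and limma on FPKM called Mir7042. A further 7 list members were called when adjusted over the list alone, 5 of them in the hypoxia list. The smallest edgeR p-values belonged to Ddit4 (ENSMUSG00000020108, chromosome 10, 59949669 to 59951834), a stress-induced inhibitor of mTORC1 (log2 fold change 1.12, SE 0.20, adjusted p = 0.951), mt-Tc (chromosome MT, 5192 to 5257), a mitochondrial tRNA gene at 79.1 CPM in WT438 and 7.41 in WT568 against 4.07 ± 0.757 in KO (mt-Tc -0.86 without WT438 in place of -3.41), Ankrd37 (1.48, SE 0.29), and the circadian repressors Nr1d1 (chromosome 11, 98767932 to 98775333, 1.07, SE 0.22) and Bhlhe40 (chromosome 6, 108660629 to 108666925, 1.02, SE 0.23), all at an adjusted p = 0.951. Without WT568 the count was 2, mt-Tc and mt-Tn.

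**Figure D3:**
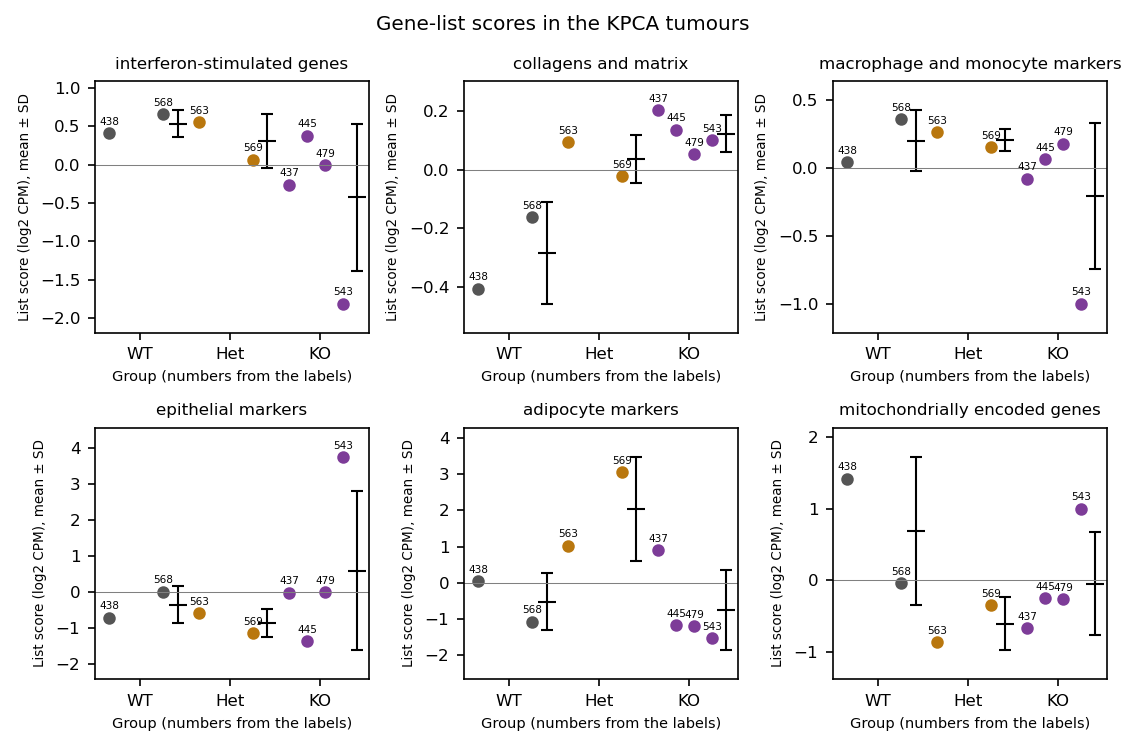
Scores of 6 gene lists in the 8 KPCA tumours, as the mean over list members of log2 CPM centred on the mean of the gene over all tumours, with 1 numbered point per tumour of the WT, Het and KO groups and bars showing the group mean ± SD. KO543 lies at -1.81 in interferon-stimulated genes and at 3.75 in epithelial markers, Het569 at 3.06 in adipocyte markers and WT438 at 1.42 in mitochondrially encoded genes.

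KO tumours were also compared with Het tumours. Adipocyte and mesothelial markers, interferon-stimulated genes and NF-kB targets were lower in KO, and BMP-SMAD targets higher. These lists passed only with the preset correlation (adjusted p from 0.404 to 0.493 with an estimated correlation), and BMP-SMAD targets were lost without Het563 or KO543. All 7 adipocyte markers were lower (median log2 fold change -3.52), and the adipocyte score was 3.06 in Het569 and 1.02 in Het563. Cidec (chromosome 6, 113424634 to 113435760), a lipid droplet protein gene, was at 8.74 CPM in Het569, 1.10 in Het563 and 0 to 0.601 in KO, and Retn (chromosome 8, 3655770 to 3660110), which encodes resistin, at 4.32, 0.60 and 0 to 0.491 CPM. Of 14 mesothelial markers 12 were lower (median -0.38). The hyaluronan synthase Has1 (chromosome 17, 17843323 to 17855205) was at 3.08 ± 0.488 CPM in KO (SD, n = 4) against 9.74 ± 1.64 in Het (n = 2) and Prg4 (chromosome 1, 150449412 to 150466165) at 2.88 ± 1.57 against 6.04 ± 4.37 CPM, a log2 fold change of -1.06 that was -0.0371 without Het569 and -1.67 without Het563. Of 30 interferon-stimulated genes 29 were lower (median -0.44). Usp18 (chromosome 6, 121245906 to 121270917) was at 25.6 ± 13.9 against 48.5 ± 3.74 CPM and Irf9 (chromosome 14, 55603571 to 55610030) at 39.5 ± 11.2 against 54.3 ± 12.7 CPM. Of 20 macrophage markers 17 were lower (median -0.27). Itgam (chromosome 7, 128062640 to 128118491) was at 38.7 ± 14.4 against 56.6 ± 5.01 CPM and Nos2 (chromosome 11, 78920787 to 78960254) at 5.62 ± 2.51 against 10.9 ± 1.38 CPM. Of 14 BMP-SMAD targets 12 were higher (median 0.38), with Grem1 (chromosome 2, 113746164 to 113758646) at 553 ± 188 against 364 ± 58.4 CPM and Runx2 at 65.2 ± 8.83 against 54.8 ± 6.03 CPM. Of 24 AMH and BMP pathway genes 18 were higher (median 0.12). Bmpr1b (chromosome 3, 141837136 to 142169425) was at 8.55 CPM in KO543 and 0.273 to 1.11 in the other KO tumours against 0.469 ± 0.0444 in Het (Bmpr1b 0.69 without KO543 in place of 2.52 on the log2 scale), and Acvr2a (chromosome 2, 48814109 to 48903269) at 17.1 ± 2.42 against 13.4 ± 0.807 CPM. Without Het569 Cidec was at -2.84 in place of -5.00 and Retn at -1.98 in place of -4.00, and without KO437 Cidec was at -9.62. Without KO543 Usp18 was at -0.61 in place of -0.92 and Itgam at -0.31 in place of -0.55, and without Het563 Irf9 was at -0.21 in place of -0.46 and Runx2 at 0.14 in place of 0.25.

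In KO against Het 21 of 38 lists passed with the preset correlation. Adipocyte markers had camera adjusted p = 2.07e-11 and adjusted p = 0.404 with an estimated correlation, and all 4 KO tumours scored below both Het tumours (exact permutation p = 0.0667 over 15 arrangements, the smallest possible). Interferon-stimulated genes (2.07e-11), mesothelial markers (2.78e-06), mitochondrially encoded genes (6.87e-05, 12 of 12 higher), macrophage markers (0.000135), NF-kB targets (0.000262, 12 of 14 lower), cholesterol synthesis (0.000268, 22 of 24 higher), epithelial markers (0.000268, 10 of 10 higher), ERK feedback genes (0.00078, 11 of 11 higher), BMP-SMAD targets (0.0202) and AMH and BMP pathway genes (0.0352) each had adjusted p = 0.493 with an estimated correlation. The other 10 passing lists had adjusted p from 0.000561 to 0.0421 with the preset and from 0.454 to 0.613 with an estimated correlation. The remaining 17 lists had adjusted p from 0.0875 to 0.995. Mesothelial markers, NF-kB targets, interferon-stimulated genes and adipocyte markers passed whichever tumour was left out, but most of these means rest on single tumours. The mesothelial mean went from -0.50 to -0.14 without Het569 and to -0.28 without KO445. The interferon mean went from -0.48 to -0.22 without Het563, -0.25 without KO543 and -0.76 without KO445. The adipocyte mean went from -2.83 to -1.35 without Het569 and -4.58 without KO437. Without KO543 BMP-SMAD targets (0.13 from 0.37), AMH and BMP pathway genes (0.13 from 0.28), macrophage markers (-0.12 from -0.31), the mitochondrial list (0.21 from 0.70), ERK feedback genes (0.14 from 0.36) and epithelial markers (0.80 from 3.25) no longer passed. Without Het563 BMP-SMAD targets (0.03), AMH and BMP pathway genes (0.33) and the mitochondrial list (0.32) were lost, and without Het569 AMH and BMP pathway genes (0.27) and cholesterol synthesis (-0.00155 from 0.21, and 0.47 without Het563). The mitochondrially encoded transcripts mt-Co2 (chromosome MT, 7013 to 7696) and mt-Atp6 (chromosome MT, 7927 to 8607) stood at 125 and 47.0 CPM in KO543 and at 36.4 ± 5.28 and 12.1 ± 2.28 CPM in Het, and without KO543 their log2 fold changes were 0.32 for mt-Co2 in place of 0.85 and 0.54 for mt-Atp6 in place of 1.05.

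No gene was called between KO and Het by edgeR, with 278 at an unadjusted p under 0.05 where chance gives 814. That count was 158 without Het563, 64 without Het569, 562 without KO445, 435 with only the compared groups fitted and 1084 with the animal-number covariate. Limma on FPKM called 0 genes and DESeq2 called Car3. A further 6 list members were called when adjusted over the list alone, 4 of them adipocyte markers. The 5 smallest p-values, all at an adjusted p = 1.00, belonged to Tppp3 (chromosome 8, 105467493 to 105471526, log2 fold change -1.29, SE 0.25), the carbonic anhydrase Car3 (chromosome 3, 14863512 to 14872523, -4.30, SE 0.85, at 14.0 CPM in Het569 and -2.31 without it), the kinase Camk1g (chromosome 1, 193346346 to 193370298, 1.43, SE 0.30), Has1 (-1.66, SE 0.35) and the alarmin Il33 (chromosome 19, 29925114 to 29960718, -0.84, SE 0.18).

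Het tumours were set against WT tumours with 2 libraries in each group. The suffix on both WT columns cannot be told apart from the WT group here either. Mitochondrially encoded transcripts were lower and collagen, hypoxia and adipocyte genes higher in Het. These lists passed only with the preset correlation (adjusted p = 0.431 each with an estimated correlation), and the hypoxia list was lost without WT568 and the adipocyte list without WT568 or Het569. All 12 mitochondrial genes were lower (median log2 fold change -1.38), with mt-Nd1 at 1656 ± 382 CPM in Het (SD, n = 2) against 5764 ± 4066 in WT (n = 2) and mt-Co2 at 36.4 ± 5.28 against 110.1 ± 65.9 CPM. All 23 collagen and matrix genes were higher (median 0.31). Col6a3 (chromosome 1, 90765923 to 90843971) was at 1015 ± 39.1 against 581 ± 134 CPM and Col5a1 (chromosome 2, 27886425 to 28039514) at 1386 ± 45.6 against 1008 ± 46.8 CPM. Of 23 hypoxia and glycolysis genes 17 were higher (median 0.26). Vegfa (chromosome 17, 46016993 to 46032369) was at 447 ± 16.9 against 228 ± 3.31 CPM and the hexokinase Hk2 (chromosome 6, 82725025 to 82774454) at 129 ± 0.347 against 68.5 ± 21.4 CPM. The adipokine Adipoq (chromosome 16, 23146536 to 23158028) had no counts in WT and 0.70 and 4.26 CPM in Het563 and Het569, and 6 of 7 adipocyte markers were higher (median 2.69, unchanged with Adipoq set to its bound). Of 11 pancreas, liver and gut markers 9 were lower (median -2.26). Pnlip was at 0.241 ± 0.200 against 7.34 ± 5.05 CPM and Prss2 (chromosome 6, 41521787 to 41525079), a trypsinogen gene, at 0.960 ± 0.198 against 5.13 ± 2.20 CPM. BMP-SMAD targets showed a median of 0.01 (adjusted p = 0.971), with Smad7 at 62.2 ± 6.61 against 46.5 ± 5.92 CPM, and AMH and BMP pathway genes a median of -0.02 (adjusted p = 0.409). Without WT438 mt-Nd1 had a log2 fold change of -0.79 in place of -1.80 and mt-Co2 of -0.78 in place of -1.60.

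In Het against WT 13 of 38 lists passed with the preset correlation. Mitochondrially encoded genes (camera adjusted p = 4.39e-15), hypoxia genes (2.19e-06), collagens (3.58e-06), adipocyte markers (9.08e-05) and pancreas, liver and gut markers (0.000105) each had adjusted p = 0.431 with an estimated correlation. The other 8 passing lists ran from 0.00108 to 0.0352, with 0.431 to 0.798 with an estimated correlation, and the remaining 25 from 0.0587 to 0.971. An exact permutation test of 2 against 2 cannot go below p = 0.333. Without WT568 the hypoxia list (0.06 from 0.31) and adipocyte markers (3.69 from 3.26) were lost, the latter also without Het569 (1.80). Without WT438 the hypoxia list reached 0.73 and adipocyte markers 5.76. In turn collagens, the mitochondrial list and pancreas, liver and gut markers passed whichever tumour was left out. The mitochondrial mean nevertheless went from -1.47 to -0.53 without WT438, and that of pancreas, liver and gut markers from -1.61 to -2.91 without Het569. The edgeR test called 0 genes, with 314 at an unadjusted p under 0.05 where chance gives 814 (2912 without WT568, 194 without Het563 and 121 without Het569), DESeq2 and limma on FPKM called 0, and 1 list member was called when adjusted over the list alone. The smallest p-values, all at an adjusted p = 1.00, were those of Nr1d1 (1.16, SE 0.24), mt-Tc (-3.80, SE 0.85, and -1.24 without WT438), Rarres1 (chromosome 3, 67478972 to 67515523, 3.14, SE 0.71), the pseudogene Gm29216 (chromosome 1, 24615706 to 24616197, -2.28, SE 0.52), whose reads may be shared with a copy elsewhere, and Vegfa (0.97, SE 0.22).

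With WT and Het tumours pooled as carriers of Amhr2, 4 KO tumours faced 4 others. The lists described here passed only with the preset correlation (adjusted p = 0.411 each with an estimated correlation). Interferon-stimulated genes were lower in KO in 29 of 30 cases (median log2 fold change -0.60). Usp18 had a log2 fold change of -1.06 (SE 0.40) and Ifit1 of -1.05 (SE 0.40). All 15 class I genes were lower (median -0.50), with Psmb8 at -0.51 (SE 0.23, and -0.31 without KO543) and Psmb10 at -0.30 (SE 0.15, and -0.19 without KO543). Collagens and matrix were higher in 18 of 23 cases (median 0.30), with fibrillin Fbn1 (chromosome 2, 125300594 to 125507993) at 0.96 (SE 0.29, and 0.56 without KO543) and Col1a1 (chromosome 11, 94936224 to 94953042) at 0.52 (SE 0.17). ERK feedback genes were all higher (median 0.27). Dusp4 was at 0.68 (SE 0.24) and Dusp5 (chromosome 19, 53529109 to 53542431) at 0.96 (SE 0.43, and 0.38 without KO543). In turn 17 of 20 macrophage markers were lower (median -0.27), with Ly6c2 (chromosome 15, 75108158 to 75111970) at -1.54 (SE 0.72, -1.02 without WT568 and -2.42 without KO479) and Ccr2 (chromosome 9, 124101950 to 124113557) at -0.51 (SE 0.26). Of 14 BMP-SMAD targets 11 were higher (median 0.32). Runx2 was at 0.35 (SE 0.14) and Grem1 at 0.67 (SE 0.26). Of 22 AMH and BMP pathway genes 17 were higher (median 0.13), with Bmpr1b at 2.63 (SE 0.93, and 0.80 without KO543) and Acvr1 at 0.44 (SE 0.18). All of these named genes had an edgeR adjusted p = 0.999.

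For KO against carriers 17 of 36 lists passed with the preset correlation, led by interferon-stimulated genes (camera adjusted p = 2.04e-19), collagens and class I genes (3.28e-08 each), and ERK feedback genes and macrophage markers (1.95e-05 each). These 5, BMP-SMAD targets (0.0103), AMH and BMP pathway genes (0.0231) and matrix proteases (0.0498) had adjusted p = 0.411 with an estimated correlation. The other 9 passing lists ran from 5.53e-05 to 0.038, with adjusted p from 0.411 to 0.552 with an estimated correlation, and the 19 that did not pass from 0.0618 to 0.851. In exact permutation tests over 70 arrangements the interferon score differed by -0.847 (p = 0.0571), collagens by 0.247 (p = 0.0571) and matrix proteases by 0.251 (p = 0.0286, the smallest possible, all 4 KO tumours above the others), in 36 tests of this kind. Without KO543 the macrophage list (-0.14 from -0.33), BMP-SMAD targets (0.12 from 0.36), AMH and BMP pathway genes (0.08 from 0.26) and matrix proteases (0.14 from 0.32) were lost, the last also without WT438 (0.34), WT568 (0.28) or Het563 (0.37). The interferon list (-0.39 from -0.62), class I genes (-0.21 from -0.44) and ERK feedback genes (0.19 from 0.41) passed without KO543 at smaller means, as did class I genes without WT568 (-0.28) and collagens without WT438 (0.18 from 0.27). The edgeR test called 0 of 15205 genes, with 630 at an unadjusted p under 0.05 where chance gives 760 (967 without KO479, 380 without KO543 and 1877 with the animal-number covariate, smallest adjusted p = 0.137), limma on FPKM called 0, DESeq2 called Camk1g and Entpd4b, and 4 list members were called when adjusted over the list alone. The smallest p-values, all at an adjusted p = 0.999, were those of Camk1g (1.20, SE 0.24), Tppp3 (-1.06, SE 0.23), Has1 (-1.42, SE 0.31), Ddit4 (0.84, SE 0.18) and Prdm1 (chromosome 10, 44437177 to 44528501, 1.21, SE 0.28), a transcriptional repressor. No list passed in any of the 7 comparisons with an estimated correlation or with fry. The median and the test of a list differed in sign in 1 to 4 lists per comparison, none of which passed.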

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

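The test of spread in this part was fixed beforehand, while which genes are named was in part settled after the results were seen. It asks, in a group of 4 libraries, whether the gap from the highest or lowest library to the next is a larger part of the group's range than Dixon's limit at the 95% level. For independent, normally distributed values chance sets apart about 1 in 20 such groups. CPM values are skewed and values of 1 library can move together, as the mitochondrial ones do. A gene at 0 in all libraries of the group but 1 is always set apart, as ESM1 and Cidec were. The numbers given for chance are therefore only a guide. Among Met5a values 3 of 43 groups were set apart, where chance gives 2.1. AMHR2 reached 5250 CPM in V1 4 against 1.98 to 68.1 in the other V1 libraries. ESM1 reached 0.232 CPM in V1 4 against 0 in the others, and JUN 801 CPM in V1 1 against 205 to 290.

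Among tumour values 14 of 80 groups were set apart, where chance gives 4, and KO543 accounted for 8 of them. In KO543 mt-Nd1 was at 5480 CPM (other KO tumours 1660 to 2140), mt-Co2 at 125 (41 to 48.9), mt-Atp6 at 47 (15 to 19.9), Spred2 at 118 (84.7 to 88.8) and Bmpr1b at 8.55 (0.273 to 1.11). Its mitochondrial share was 4.33% (1.36 to 1.72), its BMP-SMAD target score 0.668 (-0.118 to -0.00731) and its matrix protease score 0.466 (-0.0127 to 0.0435). KO479 held Try4 at 0.79 CPM (0 to 0.109) and Pnlip at 1.95 CPM (0 to 0.265). KO437 held Cidec at 0.601 CPM (0 in the others) and an adipocyte score of 0.898 (-1.54 to -1.18). KO445 had an NF-kB target score of 0.237 (-0.212 to -0.148) and a mesothelial score of -1.3 (0.0649 to 0.275).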

How the results depend on the processing

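The alternatives were planned before the data were examined, except the pairs of libraries left out and the sum of MAGED4 with MAGED4B, chosen after seeing the data. The criteria for the other splits of the samples were also written after the results were seen. Over the values of named genes, 1661 kept their direction and side of the threshold, 73 newly passed (57 with no filter, 12 with DESeq2), 8 no longer passed, all of them MAGED4, and 10 changed sign. Over the passing lists 583 values were kept, 311 no longer passed and 25 changed direction. With RLE factors the lists passing were 3, 8, 10, 18, 21, 13 and 16 for V1 with V3, V1 with CTR, V3 with CTR, KO with WT, KO with Het, Het with WT and the pooled comparison. Depth limits low genes such as Amhr2, and the simulated data show how few changes of 2-fold these group sizes recover. The causes of the changes below were not tested.

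Without a filter edgeR called 75, 533, 226, 276, 154 and 63 genes in the first 6 of these comparisons and 0 in the pooled comparison. With DESeq2 the counts were 1, 66, 9, 2, 1, 0 and 2, and with limma on FPKM they were 0, 1, 1, 1, 0, 0 and 0. With only the groups compared there was 1 gene for V3 with CTR and 0 for V1 with CTR. V1 with CTR also gave 0 without V1 1 and CTR 3 together and 0 with MAGED4 and MAGED4B summed. Calls shared by V1 and V3 against CTR were 170 with no filter and 4 with DESeq2. With an estimated correlation 0 lists passed in each of the 7 comparisons, and with fry 0. The replicate numbers do not pair the Met5a samples, since 1 of 9 same-number pairs correlates over 0.1 (-0.18 to 0.289) and 2 of 9 libraries correlate best with their own number. With the replicate block 3 genes were called for V1 with V3 (BICC1, PCDHGB5 and PDPN, the same as without V1 4), 0 for V1 with CTR and 0 for V3 with CTR, and the log2 fold change of AMH for V1 with V3 was -0.0241.

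Leaving out V1 1 and CTR 3 together, G2/M genes had a mean log2 fold change of -0.0764 and DNA replication genes of -0.106 for V1 with CTR, and of -0.182 and -0.0833 for V3 with CTR. Leaving out KO543 and WT438 together, 13 lists passed for KO with Het and 21 for Het with WT. Epithelial markers were then at -0.24 and endothelial markers at 0.0545 for KO with WT, nuclear oxidative phosphorylation genes at 0.26 for Het with WT, and epithelial and endothelial markers at -0.12 and 0.11 in the pooled comparison. With the animal-number covariate Amhr2 was at 0.0392 for KO with Het.

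With single libraries left out, genes called ran from 0 to 3 for V1 with V3 (3 without V1 4), 0 to 6 for V1 with CTR (6 without V1 4), 0 to 0 for V3 with CTR, 0 to 2 for KO with WT (2 without WT568), 0 to 0 for KO with Het, 0 to 2 for Het with WT (2 without WT568) and 0 to 0 in the pooled comparison. Lists passing ran from 3 to 7, 7 to 13, 8 to 12, 7 to 23, 10 to 23, 6 to 19 and 13 to 22 in the same order. The count was 7 without V1 2 for V1 with V3, 13 without CTR 1 for V1 with CTR, 7 without WT568 for KO with WT, 10 without Het563 for KO with Het and 6 without WT568 for Het with WT. Some ranges include a change of direction, for lists their direction against all other genes. For V1 with V3 they were -6.07 to 5.36 for AMHR2 and -0.13 to 0.21 for AMH. For V1 with CTR they were 0.19 to 1.17 for interferon-stimulated genes, -0.20 to 0.53 for G2/M genes, 0.0215 to 0.41 for DNA replication genes and -0.0602 to 0.34 for AMH. For V3 with CTR they were -0.18 to 0.55 for G2/M genes, -0.0803 to 0.31 for DNA replication genes and -0.11 to 0.31 for AMH. For KO with WT they were -0.49 to 0.0786 for G2/M genes, -0.00379 to 0.66 for hypoxia genes, -1.40 to 0.15 for mitochondrially encoded genes, 0.0578 to 4.40 for epithelial markers, -1.37 to 1.01 for T cell markers, -1.59 to 1.55 for cytotoxic cell markers and -1.73 to 0.15 for mt-Nd6. For KO with Het they were -0.00155 to 0.47 for cholesterol synthesis, -0.96 to 0.30 for B cell markers and -0.72 to 0.27 for Amhr2. For Het with WT they were 0.0607 to 0.73 for hypoxia genes and -0.59 to 0.27 for nuclear oxidative phosphorylation genes, and in the pooled comparison -0.0765 to 3.08 for epithelial markers.

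Other splits of the samples, each fitted on the compared groups alone, decide nothing about genes called where the real value is 0, because every split reaches it. That gave 35 of 35 splits for V1 with V3 (real 0, highest other 25), 35 of 35 for V1 with CTR (real 0, highest other 3) and 35 of 35 in the pooled comparison (real 0, highest other 3). The split with 25 genes set V1 2, V1 3, V3 2 and V3 3 against the rest. The rest included V1 4 and V3 1, the most alike pair of Met5a libraries (r = 0.991). This split is the highest of 35, and why it stood out was not tested. Chance could not be excluded for the lists passing, with 29 of 35 splits for V1 with V3 (real 5, highest other 14), 22 of 35 for V1 with CTR (real 8, highest other 13) and 6 of 35 in the pooled comparison (real 17, highest other 21). For V3 with CTR the 10 splits are too few for a share under 0.05, with a real value of 1 gene (2 of 10 splits, highest other 3) and 11 lists (5 of 10 splits, highest other 16).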

Other observations

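All tests of explanations in this part were chosen after the results were seen. In V1 cells 9 of 13 mesothelial markers were lower than in CTR (median log2 fold change -0.27, camera adjusted p = 0.0943, adjusted p = 0.436 with an estimated correlation). CALB2, which encodes calretinin (chromosome 16, 71358713 to 71390438), was at 2.46 ± 2.69 CPM in V1 (SD, n = 4), 4.66 ± 1.71 in V3 (n = 3) and 30.4 ± 23.6 in CTR (n = 3). Its edgeR adjusted p was 0.569 for V1 with CTR.

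Between KO and Het tumours further lists passed camera with the preset correlation. All 15 class I genes were lower (adjusted p = 0.000561, adjusted p = 0.563 with an estimated correlation), and the list was lost without Het563 or without KO543, the mean log2 fold change then being -0.05 in both cases in place of -0.28, while it reached -0.48 without Het569 and -0.42 without KO437. Cytotoxic cell markers were lower in 6 of 8 cases (0.00439) and neutrophil markers in 6 of 8 (0.0421), each with adjusted p = 0.493 with an estimated correlation. Cytotoxic cell markers were lost without KO445, and neutrophil markers without Het563, Het569, KO445 or KO543. Immediate-early genes were higher in 14 of 15 cases (0.0151, adjusted p = 0.541 with an estimated correlation) and were lost without Het563, KO437 or KO543, with means of 0.56, 0.38 and 0.32 in place of 0.61. B cell markers (6 of 7 lower, 0.0352, adjusted p = 0.493 with an estimated correlation) turned from a mean of -0.74 to 0.30 without Het563 and were also lost without KO437, KO445 or KO543.

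ACVR1 rose with AMHR2 from library to library among the 7 V1 and V3 libraries. Pearson's r of log2 CPM was 0.98 (exact permutation p = 0.000198 over 5040 arrangements) and Spearman's rho 1 (p = 0.000397), and without V1 4 and V3 1 r was 0.889 (exact p = 0.075 over 120 arrangements) and rho 1 (p = 0.0167). Reads of AMHR2 assigned to ACVR1 would keep a fixed ratio, but the excess of ACVR1 over AMHR2 ranged 18.2-fold between libraries, which argues against them, and a general shift of the 2 libraries with the most AMHR2 is argued against by only 2 of 58735 genes, ACVR1 and AMHR2, being over 2-fold higher in both than in every other library. That both receptors were introduced together stays open, as does a response of ACVR1 to the receptor in either form, since both predict the correlation of 0.98. A response that needs the active form is argued against by the V3 libraries, if V3 is inactive as described. ACVR1 was at 7200, 327 and 79.7 CPM in V3 1 to 3, against 26.4 to 27.2 CPM in CTR.

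The interferon-stimulated genes of KO tumours may reflect 1 tumour or the cells in the tumours. The score difference from the pooled others was -0.847 (exact permutation p = 0.0571 over 70 arrangements) and -0.385 without KO543 (p = 0.143 over 35), so that tumour alone is neither required nor excluded. Library depth is not excluded: 4 of 4 KO totals lie inside the range of the others, but WT438 and WT568 set it. The score followed the macrophage score with r = 0.959 over 8 tumours (exact permutation p = 0.00543, rho 0.762, p = 0.0368), and without KO543 and WT568 r was 0.538 (p = 0.265) and rho 0.429 (p = 0.419), so the relation rests on those tumours. Depth, fewer macrophages and genotype stay open.

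V1 4 and V3 1 were the most alike Met5a libraries, with r = 0.991 over genes, which are not independent. Their counts differed by a chi-square per degree of freedom of 3.5, more than counting noise gives, which argues against 1 library deposited more than once, while every other Met5a pair was at 23.1 or more and pairs of the same group at 24.5 or more. They are thus closer than any replicates, and 1 shared sample stays open. A profile set by the AMHR2 level stays open. CTR 2, without AMHR2 counts, correlated with V3 1 at 0.987, above the 0.97 of the best other V3 library. That rests on 1 library (CTR 1 was at 0.971, CTR 3 at 0.937). A mislabelled sample stays open. V1 4 correlated at up to 0.967 with other V3, 0.954 with other V1 and 0.987 with CTR libraries. The last was CTR 2 (chi-square 23.1), and what it shares with the pair was not tested.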
